A study of Mus musculus with 4 samples.

How the data were processed

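Total RNA was the starting material of 4 sequencing libraries of cells sorted from the cochlear epithelium of C57BL/6 mice at postnatal day 7. The mice carried a Sox2-driven, tamoxifen-activated Cre recombinase, a Cre-dependent Atoh1 transgene, an Atoh1-eGFP reporter and a Cre-dependent tdTomato reporter. Tamoxifen was given at 0.20 mg per g of body weight on postnatal day 3, per the labels. Sox2 marks cochlear supporting cells, so Cre switched on Atoh1 and tdTomato there. The sort collected cells with eGFP alone, called original hair cells, and cells with both eGFP and tdTomato, called new hair cells. Each group had 2 libraries. The labels do not say whether these came from separate animals or pools. Libraries were made with the SMART-Seq v4 low-input kit, per the labels' protocols.

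Per the submitters' processing notes, CASAVA 1.8, Trimmomatic and TopHat were used with genome build mm10. The program that computed expression and the test behind the p-values are not given in the sources used here. The deposited table held FPKM (fragments per kilobase of transcript, relative to all mapped fragments) as 1 value per gene and group, per the file headers. The authors therefore pooled or averaged the 2 libraries of each group, and which of these they did is not given in the sources used here. The deposited table also held a log2 ratio of new over original and an unadjusted p-value per gene, as the authors gave them. No value per library and no read count was used here, so the depth of each library is unknown, and no SD, interval or detection floor of its own could be given.

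The table had 23996 rows with a gene. The content of 1 further row was not analysed here. Of these rows, 105 named more than 1 gene and 5315 shared their locus with another row, so reads may be divided between such genes. The deposited log2 ratio was checked against the ratio of both FPKM columns. For 3 genes the deposited log2 was 0 and the p 1 although their FPKM values differed. These were left out of the tested genes and of all comparisons between groups. Counts of rows, counts of genes above 0 or at an FPKM level within 1 group, and the FPKM sums include them. Apart from these 3 genes, 4 genes differed by more than 0.01 without a change of sign, by 0.08 in Cnbp, 0.43 in Eif4a1, 0.65 in Sept7 and 1.53 in Vdac3. Their folds were taken from the FPKM columns, like those of all genes. Where 1 group was at 0, the deposited log2 cell held text, in 3311 genes. Such genes are described as listed at 0, with no fold. Starts of loci were compared with the GENCODE annotation of mm10. Of 6746 genes with the same end, 3116 began exactly 1 base lower, so 1 was added to each printed start.

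Genes with at least 1 FPKM in at least 1 group and above 0 in both were analysed, which left 9026 genes, called tested genes below. Differences were taken as log2(FPKM + 1) of new minus original. The pseudocount of 1 understates the change of low genes. Folds printed for single genes are plain ratios of FPKM. The deposited p-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. The planned tests across libraries (limma for FPKM values, camera for gene lists) need a value per library and could not be fitted.

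Gene lists were fixed before the data were examined, as were the rule for named genes and the first set of other settings. The 39 lists covered hair cells and their subtypes, supporting cells, other cochlear cell types, signalling pathways, ion channels, cell cycle, stress and housekeeping functions. For each of the 31 lists with at least 5 tested genes, the median difference was set against 10000 random lists of the same size. Random genes were drawn with replacement within 20 bins of mean level. The percentile of the list's median is a description of these libraries and not a test across animals. The procedure was tested on simulated lists of 20 genes drawn from the 9026 tested genes. Without a shift 4 of 100 lists fell outside the central 95%, against 47 with a shift of -1 and 97 with a shift of -2 on the log2 scale. The simulated genes were drawn independently, so this does not cover lists whose genes vary together, or lists of other sizes.

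Named genes were those of the 10 largest rises and 10 largest falls with at least 5 FPKM in the higher group, leaving out clone and predicted names. None passed the adjusted threshold, so these were filled by size of change. The rule fixed in advance also asked that both libraries of one group lie above both of the other. That could not be checked with 1 value per group and was dropped. To them came the 2 tested genes of highest mean per list and 18 genes fixed in advance. Any other gene named was chosen after its values were seen, including further list members given as examples. Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, a trimmed-mean scaling (30% of ratios and 5% of levels trimmed at each end) and quantile normalization. A scaling of both groups to equal FPKM sums, other ways of matching the random lists, and leaving out rows that share a locus were added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.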

Results

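Hair cells are the sensory receptor cells of the cochlea, and supporting cells are the epithelial cells around them. Atoh1 is the transcription factor that starts hair cell development. The comparison set hair cells induced from supporting cells by Atoh1 overexpression (new, 2 libraries) against hair cells that arose in normal development (original, 2 libraries), to characterize the transcriptome of the induced cells. The deposited table gave 1 FPKM value per gene and group, so no value below has a replicate error, and no difference could be set against the spread between libraries. Depth per library is unknown. In original hair cells 15383 genes had an FPKM above 0, and in new hair cells 16361. At least 1 FPKM was reached by 7744 and 7808 genes.

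The FPKM sums of both columns differed. FPKM summed to 2165833 in original and 244225 in new hair cells, an 8.87-fold difference or 3.15 on the log2 scale. At least 1000 FPKM was reached by 426 genes in original and 20 in new hair cells. The 100 most abundant genes held 48.4% of the sum in original and 36.6% in new hair cells. Low and high quantiles did not share this difference. Over the tested genes, new minus original was 0.07 at the 25th percentile of log2 FPKM and -3.10 at the 95th. Directions below are on the deposited scale, and scaling to equal sums would add 3.15 to each log2 ratio. Counts of list members higher with equal sums include this shift of all genes. Across the 9026 tested genes the median log2 difference of new minus original was -0.21, which moved to 0.06 with trimmed-mean scaling, 0.26 with quantile normalization and 2.53 with equal sums. Spearman's rho between both columns was 0.49 across genes, which are not independent replicates.

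Inner hair cell genes were lower in new hair cells in 7 of 8 cases, and supporting cell genes were higher in 26 of 35. Otof, needed for transmitter release at the hair cell synapse, was 158-fold lower, at 1945 FPKM in original and 12.3 in new hair cells. Myo7a, a motor protein of the hair bundle, was 89.9-fold lower (159 and 1.77 FPKM). Epyc and Fabp7, both in the supporting cell list and Fabp7 in that of Schwann cells and glia too, stood at 97.0 and 72.4 FPKM in original and at 725 and 278 FPKM in new hair cells. Of the tested genes, 1793 were at least 2-fold higher in new hair cells and 3149 at least 2-fold lower on the log2(FPKM + 1) scale. Those higher made up 36.3% of both, against 54.6% after quantile normalization (2808 higher, 2332 lower) and 82.3% after scaling to equal sums (6278 higher, 1354 lower). No gene passed an adjusted p of 0.05 when the p-values in the authors' deposited table were adjusted by the Benjamini-Hochberg method, the smallest adjusted p being 0.526. At an unadjusted p under 0.05 in the authors' deposited table, 50 tested genes were higher and 797 lower in new hair cells, where chance alone gives 451.3 in all.

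**Figure D1:**
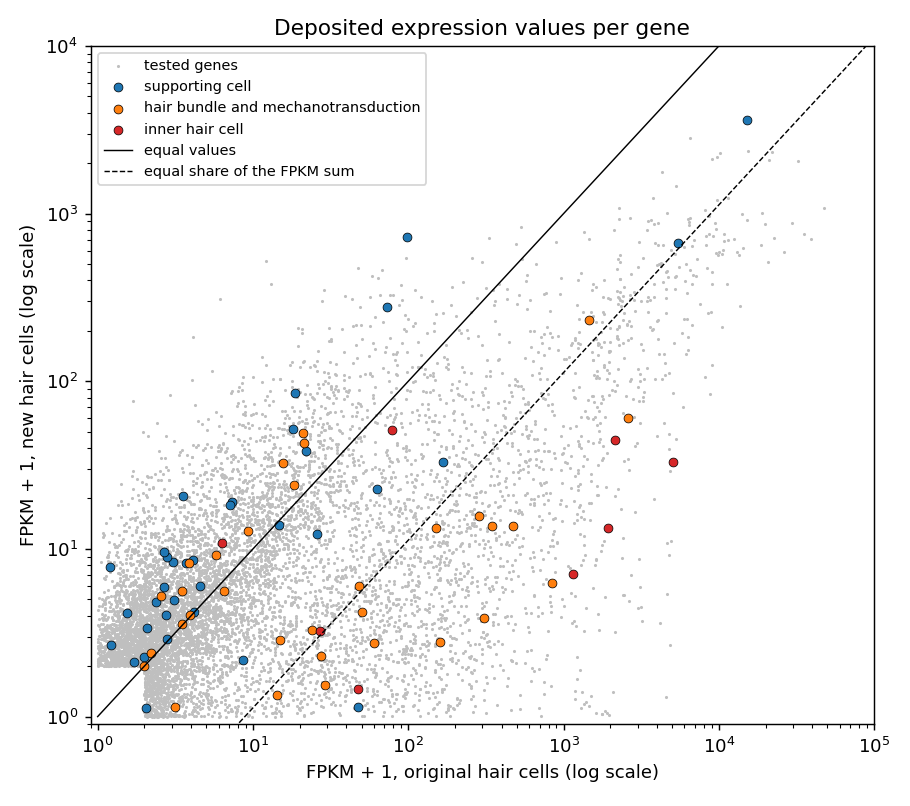
FPKM + 1 of each of the 9026 tested genes in original (x axis) and new hair cells (y axis), both on log scales, 1 point per gene. Coloured points are 3 gene lists, the solid line marks equal values and the dashed line values equal after scaling to the same FPKM sum. Of 8 inner hair cell genes 7 lie below the solid line, and of 35 supporting cell genes 26 lie above it.

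The induced gene itself was examined first. Atoh1 (mm10, chromosome 6, 64729146 to 64731235) stood at 791 FPKM in original and 83.4 FPKM in new hair cells, 9.48-fold lower in the group labelled new, with p = 0.186 in the authors' deposited table. After scaling to equal sums its log2 ratio was -0.10. Transgene and endogenous transcripts were not separated in the table, and both groups were sorted for an Atoh1 reporter. Atoh1 therefore gives only a weak check of the labels, and directions are those of the groups as labelled.

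Hair cell transcription factors did not stand apart as a list. Of 11 tested members 6 were higher and 5 lower in new hair cells, and the median difference of 0.10 lay at percentile 90.3 of random lists. Pou4f3, required for hair cell survival, was at 16.7 FPKM in original and 16.1 FPKM in new hair cells, lower on the deposited scale and higher under each of the other 3 scalings. Gfi1 was 28.9-fold lower (86.2 and 2.98 FPKM), with p = 0.0487 in the authors' deposited table. Isl1 was 11.2-fold lower (467 and 41.6 FPKM). Lhx3 stood at 3.59 FPKM in original and 16.5 FPKM in new hair cells.

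Inner hair cell genes were the list farthest below random lists. Of 8 tested members 7 were lower in new hair cells, with a median log2 difference of -5.32 at percentile 0.16, and the median stayed below 0 under every scaling tried. Adjusted over the list alone, 4 members passed 0.05 using p-values of the authors' deposited table, all lower in new hair cells, and none passed over all tested genes. These were Otof, Atp2a3, a calcium pump (1144 and 6.08 FPKM), Fgf8, a secreted growth factor (5068 and 32.0 FPKM), and Slc17a8, the glutamate transporter that fills synaptic vesicles (46.7 and 0.454 FPKM). The p of Otof was 0.0023 and that of Slc17a8 0.014 in the authors' deposited table. Calb2 was 49.3-fold lower (2148 and 43.5 FPKM).

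Of 8 tested outer hair cell genes, 7 were lower in new hair cells, but the median of -3.11 lay at percentile 16.7, within the range of random lists of like level, and at 1.07 when matched on the new FPKM alone. Ocm, a calcium-binding protein of outer hair cells, was 44.0-fold lower (26071 and 592 FPKM). Slc26a5, which encodes the motor protein prestin, was 14.8-fold lower (55.8 and 3.77 FPKM), with p = 0.0123 in the authors' deposited table. Scaled to equal sums, 4 of the 8 were higher and 4 lower, with a median of -0.14. Relative to the median of all tested genes that was -2.67, against -2.90 in the main setting.

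Hair bundle and mechanotransduction genes were split. Of 32 tested members 19 were lower and 13 higher in new hair cells, and the median of -2.52 lay at percentile 0.42, below the central range of -1.93 to 0.25. An unadjusted p under 0.05 in the authors' deposited table was reached by 6 members, all lower, and none passed when adjusted over the list alone. Lhfpl5, a part of the transduction channel complex, was 43.6-fold lower (2595 and 59.5 FPKM) and Myo6 19.4-fold lower (284 and 14.6 FPKM). Cib2 was 6.31-fold lower (1457 and 231 FPKM), but higher after quantile normalization or scaling to equal sums. Tmc1, a pore subunit of the channel, stood at 47.1 and 4.98 FPKM, while Tmc2 was under the 1 FPKM filter in both groups. Espn, an actin bundler of the bundle, was at 20.1 FPKM in original and 47.9 FPKM in new hair cells. The list's percentile moved to 58.3 without a filter on low genes. With equal sums its median moved to 0.07, but its percentile was 0.18. Relative to the median of all tested genes the list stood at -2.31 in the main setting and -2.46 with equal sums.

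Genes of the hair cell synapse and conductances were lower in 11 of 16 cases, at percentile 15.3, and only Otof passed when adjusted over the list alone, using p-values of the authors' deposited table. With equal sums 12 of the 16 were higher, but their median relative to that of all tested genes went from -0.72 to -1.06. Voltage-gated potassium channel genes were lower in 13 of 18 cases, with a median of -0.95 at percentile 1.57. With equal sums their median turned to 1.23, where that of all tested genes was 2.53. Relative to the median of all tested genes they stood at -0.74 in the main setting and -1.31 with equal sums. Kcnma1, a calcium-activated potassium channel, was 241-fold lower (94.1 and 0.390 FPKM), with p = 0.00865 in the authors' deposited table. Their percentile left the lower tail without a filter (7.11), after quantile normalization (2.56), without rows sharing a locus (2.90) and when matched on the new FPKM alone (49.4).

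Supporting cell genes stood above random lists. Of 35 tested members 26 were higher and 9 lower in new hair cells, and the median of 0.80 lay at percentile 99.98. It stayed above 0 under every scaling, but each of the other scalings raised the median of all tested genes too. Relative to that median the list stood 1.01 higher in the main setting, and 0.91 to 1.16 higher under the other scalings. None of the 35 members reached p under 0.05 in the authors' deposited table. Sox9 stood at 1.36 and 3.80 FPKM, Hes5 at 6.30 and 17.9 FPKM, and Jag1 at 3.53 and 5.03 FPKM in original and new hair cells. Cdkn1b, an inhibitor of cell division, was 4.42-fold higher in new hair cells, at 7.98 FPKM. Members of high level went both ways on the deposited scale. Beside Epyc and Fabp7, S100a1 was 4.20-fold lower (15179 and 3617 FPKM), Fbxo2 8.12-fold lower (5421 and 667 FPKM) and Sox2 2.81-fold lower (61.5 and 21.8 FPKM), and these 3 were higher in new hair cells after quantile normalization or scaling to equal sums. Prox1 was under 1 FPKM in both groups.

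**Figure D2:**
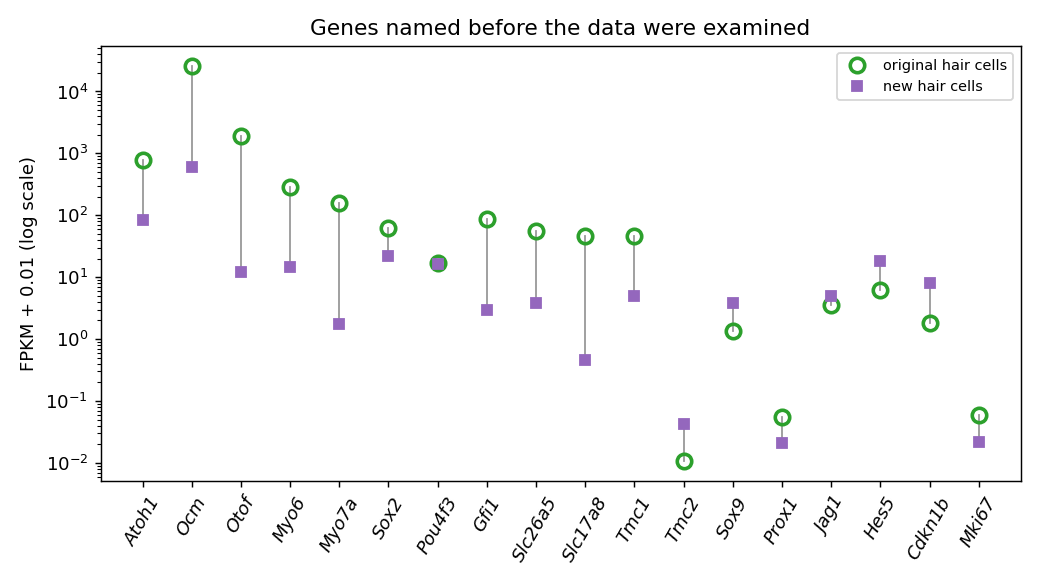
FPKM + 0.01 on a log scale for the 18 genes fixed in advance, with open circles for original and squares for new hair cells, 1 deposited value per group and no error bars. Slc17a8, Otof and Myo7a lie 103-fold, 158-fold and 89.9-fold lower in new hair cells, and Pou4f3 at 16.7 and 16.1 FPKM.

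Signalling pathways differed in their place. TGF-beta and BMP pathway genes were higher in new hair cells in 13 of 17 cases, with a median of 1.27 at percentile 99.97. It stayed above 0 under the other scalings, each of which raised the median of all tested genes too. Relative to the latter the list stood 1.48 higher in the main setting, and 1.11 to 1.48 higher under the other scalings. No higher member reached p under 0.05 in the authors' deposited table. Id1, a BMP target, was at 66.6 FPKM in original and 459 FPKM in new hair cells, while Id4 was 16.9-fold lower (468 and 27.7 FPKM). Notch pathway genes were higher in 12 of 22 cases at percentile 77.1 (15 after quantile normalization and 20 with equal sums), with Hes6 at 120 and 318 FPKM and Rfng 27.8-fold lower (103 and 3.70 FPKM). Wnt pathway genes were higher in 12 of 21 cases at percentile 93.9 (13 after quantile normalization and 16 with equal sums). Wnt5a was 132-fold lower (351 and 2.66 FPKM), with p = 0.0019 in the authors' deposited table, and passed when adjusted over the list alone. FGF pathway genes were higher in 5 of 10 cases at percentile 47.2, with Fgfr1 107-fold lower (246 and 2.29 FPKM).

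Markers of other cochlear cell types were examined because the sort could hold such cells. Spiral ganglion neuron markers were lower in 5 of 8 cases, with a median of -3.27 at percentile 0.87. Nefl, a neurofilament subunit, was 1192-fold lower (3214 and 2.70 FPKM) and Pvalb 73.6-fold lower (9074 and 123 FPKM), and both passed when adjusted over the list alone, with p-values of the authors' deposited table. Pvalb and Calb2 of this list are also hair cell genes, and Calb2 stands in the inner hair cell list. The percentile left the lower tail with a pseudocount of 0.1 (2.52), without a filter (26.6) and with equal sums (2.57), where 4 of the 8 were lower. Mesenchyme and fibroblast markers lay at percentile 19.2, Schwann cell and glia markers at 61.6 and macrophage and immune cell markers at 93.9. The mesenchyme list entered the lower tail with a pseudocount of 0.1 (1.53), a filter of 5 FPKM (1.8), quantile normalization (1.62) and equal sums (0.83). The Schwann cell list entered the upper tail with a filter of 5 FPKM (98.2) and without rows sharing a locus (99.5), and the macrophage list when matched on the new FPKM alone (98.7). Of 14 tested mesenchyme markers, 5 were higher and 9 lower in new hair cells. Otor, a mesenchyme marker of the cochlea, stood at 1383 FPKM in original and 0.226 FPKM in new hair cells. Lum of the same list went the other way, at 89.4 and 375 FPKM. Of 8 tested Schwann cell and glia markers, 4 were higher and 4 lower. Fabp7 was higher, while Cnp was 246-fold lower in new hair cells, from 983 FPKM in original. Of 5 tested macrophage and immune cell markers, 3 were higher and 2 lower. Tyrobp, an immune cell adaptor, stood at 3.24 and 71.7 FPKM.

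Cytosolic ribosomal protein genes were lower in 69 of 81 cases, with a median of -2.59, above the median of -3.44 of random lists of like level (percentile 100.0). With equal sums 63 of the 81 were higher in new hair cells, and after quantile normalization 61, against 12 in the main setting. Relative to the median of all tested genes the list stood at -2.38 in the main setting, -1.97 with equal sums and 0.40 after quantile normalization. The percentile was 12.3 when matched on the new FPKM alone and 69.3 when matched on exon length as well. Oxidative phosphorylation genes were lower in 62 of 79 cases, with a median of -3.45 at percentile 23.2. Cox6a1 was 54.9-fold lower (38908 and 708 FPKM). Scaled to equal sums, 48 of the 79 were lower. The percentile of this list was 98.1 when matched on the original FPKM alone and 0 when matched on the new FPKM alone, and 2.08 when matched on exon length as well.

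Lists of cell cycle, stress and metabolism lay inside the range of random lists in the main setting. Cell cycle genes were at percentile 58.3 with 11 tested members, and the proliferation marker Mki67 was under 1 FPKM in both groups. With a filter of 5 FPKM the list lay at 97.545, just past the upper limit. Cell cycle inhibitors lay at percentile 94.7, and at 98.4 when matched on the original FPKM alone and 97.7 without rows sharing a locus, with Cdkn2d 39.1-fold lower (1355 and 34.7 FPKM). Genes of p53 and apoptosis lay at percentile 33.3, immediate early and stress genes at 46.5, the unfolded protein response at 84.8, and glycolysis at 88.8. Gapdh stood at 568 and 394 FPKM, and turned to higher in new hair cells after quantile normalization or scaling to equal sums.

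Other families lay inside that range too in the main setting. Extracellular matrix genes were at percentile 76.8, epithelial junctions at 83.9, cilia genes at 26.9, unconventional myosins at 5.78, and the SOX family at 96.4. Calcium channel genes were at percentile 97.3, transient receptor potential channels at 78.2 and solute carriers at 69.0. Among solute carriers only Slc7a1, an amino acid transporter (246 and 0.574 FPKM), passed when adjusted over the list alone, using p-values of the authors' deposited table. Of these, extracellular matrix genes left the range after quantile normalization (99.6) and the SOX family when matched on the original (99.4) or new FPKM alone (98.6). Calcium channels left it without a filter (97.8), with trimmed-mean scaling (97.7) and when matched on the new FPKM alone (98.3). The remaining 8 lists had fewer than 5 tested genes and were not placed. In all, 7 of 31 lists lay outside the central 95% of random lists, 4 below and 3 above. For lists of genes that vary independently 1.55 would lie outside. Genes of a list may vary together and some stand in more than 1 list, so no excess can be read from this.

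**Figure D3:**
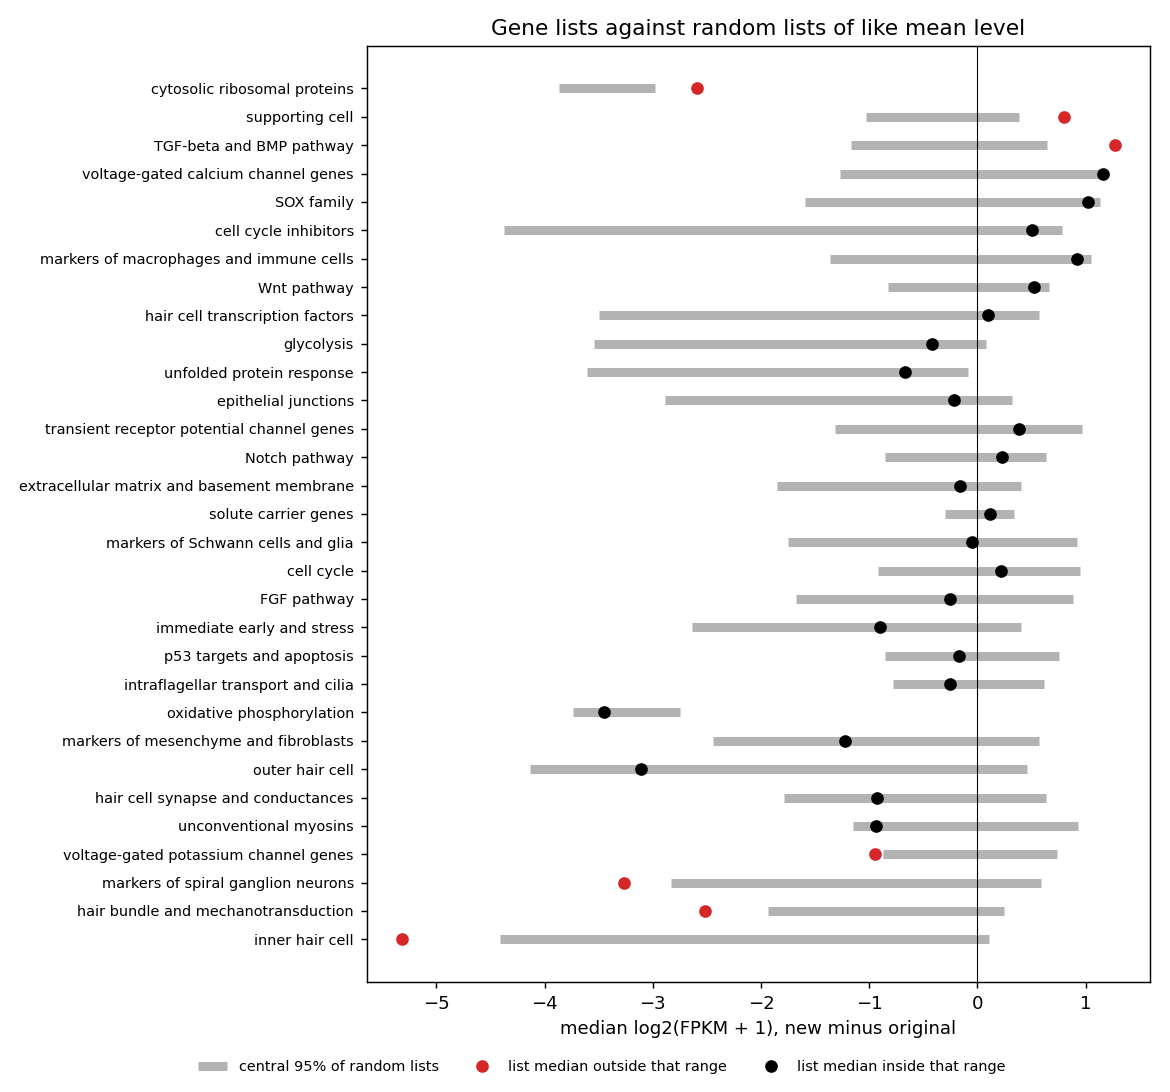
Median log2(FPKM + 1) difference, new minus original, of 31 gene lists (points) beside the central 95% of 10000 random lists of like mean level (grey bars). Red points mark the 7 lists outside that range, from inner hair cell genes at -5.32 to TGF-beta and BMP pathway genes at 1.27. The zero of the x axis is on the deposited scale.

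Single genes with the largest differences were not those with the smallest p. The largest rises were Saa3, an acute phase protein (5.15 and 307 FPKM), Ifi27l2a (0.697 and 74.9 FPKM), Oc90, a protein of otoconia (3.11 and 182 FPKM), Vmo1 (11.2 and 524 FPKM) and Npy, a neuropeptide (31.7-fold higher, at 380 FPKM). After them came Camp, Bst2, Dapl1, Tmem37 and Lzts2. Of these 10, 7 had p under 0.05 in the authors' deposited table. The largest falls were Mgp, an inhibitor of calcification (4583 and 0.307 FPKM), Upk3a (1966 and 0.0186 FPKM), Nupr1 (4825 and 1.68 FPKM), Ripply2 (1890 and 0.0567 FPKM) and Adm (1859 and 0.0786 FPKM). After them came Ifitm3, Car3, Cela1, Poll and Sfn. Of these 10, 2 had p under 0.05 in the authors' deposited table, Nupr1 and Poll. None of the 20 passed after adjustment. All 20 kept their direction under every scaling tried, but they were picked for the size of their differences. Trimmed-mean scaling and equal sums raise each log2 ratio, by 0.35 and 3.15. The rises could thus only grow there, and the falls, at -10.3 or below, could not turn.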

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

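The scaling to equal sums, the other ways of matching random lists, the removal of rows sharing a locus and the restriction to genes with p below 1 were chosen after seeing the data. Counts at least 2-fold higher in new hair cells were 1793 in the main setting, 1165 with a filter of 5 FPKM, where fewer genes were tested, 2808 after quantile normalization and 6278 with equal sums. Those at least 2-fold lower were 3149, and 1354 with equal sums. Genes higher at a p under 0.05 in the authors' deposited table numbered 50, and 53 without a filter. They numbered 85 when genes at 0 in 1 group were counted too, or over genes with p below 1, since 32 such genes entered. The count past the adjusted threshold was 0 in both directions in each of these settings. The number of lists outside the central 95% ranged from 7 to 10. Inner hair cell genes stayed at percentiles 0.01 to 0.82, supporting cell genes at 99.77 to 100.0 and TGF-beta and BMP genes at 97.71 to 99.99. Hair bundle genes reversed to percentile 58.3 without a filter, and ribosomal protein genes to 12.3 when matched on the new FPKM alone. The cause was not tested for either. Of 97 named genes, 1 changed sign with trimmed-mean scaling, 14 after quantile normalization and 17 with equal sums, none of them among the 33 with p under 0.05. Of these 33, the lower ones stood at -3.58 or below, past the shift of 3.15 with equal sums, and the higher ones could only rise. Trimmed-mean scaling and equal sums therefore could not have turned any of the 33. No paired analysis was possible because the deposited table held 1 value per group. For the same reason the fits without each replicate, limma without trend, camera with an estimated correlation and fry were not run. Depth per library is unknown and sets no limit that could be stated here.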

Other observations

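All tests of explanations below were chosen after the values were seen. Among genes picked after their values were seen, collagen genes went both ways, as did the extracellular matrix list, with 12 members higher and 12 lower. Col9a1, Col9a2 and Col9a3 stood at 8.99, 7.46 and 6.98 FPKM in original and 105, 96.7 and 73.2 FPKM in new hair cells. Col1a2, Col3a1 and Col5a1 stood at 308, 152 and 136 FPKM in original and 3.54, 1.91 and 0.282 FPKM in new hair cells. The Col9 genes were higher and these others lower under scaling to equal sums as well. Id3 went from 79.2 to 326 FPKM and Fgfr3, a supporting cell receptor, from 2.57 to 19.6 FPKM.

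Interferon-stimulated genes, a list written after Bst2 and Ifi27l2a were seen among the largest rises, were split. Of 15 tested members 8 were higher and 7 lower in new hair cells, and the median of 0.19 lay at percentile 80.9 of random lists. H2-K1 stood at 840 and 10.3 FPKM and Bst2 at 0.951 and 48.6 FPKM. Apart from the 3 genes with unlike values and a deposited log2 of 0 (Skp1a, Malat1 and Clu), 34 genes were listed at 0 in original and at or above 1 FPKM in new hair cells, and 122 the other way. As deposited, Malat1 stood at 1811 and Clu at 2905 FPKM in original hair cells, and both were listed at 0 in new hair cells. Skp1a stood at 1312 FPKM in new and was listed at 0 in original hair cells. The deposited log2 of these 3 genes does not match their values, so no difference is read from them. At least 100 FPKM in original and under 1 FPKM in new hair cells was found for 118 genes, against 0 the other way.

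Abundant genes were lower in new hair cells relative to other genes. One scaling factor would shift all quantiles of log2 FPKM alike, but over the tested genes new minus original was 0.07 at the 25th percentile and -3.10 at the 95th (3.22 and 0.05 with equal sums), a difference of -3.18 with a bootstrap interval over genes of -3.49 to -3.02. Exon length did not account for it, since within each of 4 length classes that difference was -3.22 or lower. A few very abundant genes did not account for the unlike FPKM sums, which still differed 7.01-fold without the 100 most abundant genes of each group. That ratio does not measure the unequal shift of quantiles and decides nothing about it. Among genes of at least 1 FPKM in the column used, the median log2 ratio in the highest of 10 bins was -4.54 by original and -1.29 by new FPKM, and -1.39 and 1.86 with equal sums, so abundant genes were not lower outright under each scaling. A difference in RNA amount or amplification between low-input libraries, and a biological difference between original and new hair cells, stay open as untested. Either may be the source, and so may others that were not looked at.

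Atoh1, the overexpressed gene, was lower in the group labelled new. Swapped labels would put inner hair cell genes above and supporting cell genes below random lists, but these lay at percentiles 0.16 and 99.98. That prediction assumes less inner hair cell and more supporting cell expression in induced cells, which was not tested apart from these labels. The percentiles therefore cannot settle whether the labels were swapped. Whether Atoh1 only follows the trend of genes of its level stays open, since the answer moves with the definition of level. Its log2 ratio lay at percentile 56.3 among 451 genes of like mean level, at 73.6 by original FPKM and at 18.8 by new FPKM. The deposited values do not separate transgene from endogenous Atoh1.

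Tyrobp and Fcer1g, both immune cell adaptors, stood at 71.7 and 28.7 FPKM in new against 3.24 and 1.83 FPKM in original hair cells. Of 20 myeloid-associated genes looked at after the values were seen, 7 were higher (Camp at 1.94 and 81.5, Prtn3 at 0.423 and 23.2, Wfdc17 listed at 0 and at 40.8 FPKM) and 12 lower in new hair cells (S100a9 at 1.65 and 0.0397, C1qb at 2.08 and 0.364 FPKM). Apart from S100a9 and C1qb, the lower ones were under 1 FPKM in both groups, so their direction says little. Ltf among the higher ones was under 1 FPKM in both groups too, while the other higher ones reached at least 23.2 FPKM in new hair cells. Macrophages in the sort would bring their abundant transcripts too, but the highest of 8 such genes, among them Lyz2, Cd74, Csf1r and C1qa, reached 0.364 FPKM in new hair cells. Granulocytes in the sort stay open, since of 9 of their transcripts 2, Camp and Prtn3, reached 1 FPKM in new hair cells, while the others, among them S100a8 and S100a9, were at 0.230 FPKM or lower. The sort took cells by eGFP and tdTomato, its purity was not measured here, and no biological explanation was tested.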
